A study of Drosophila melanogaster with 10 samples.

How the data were processed

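RNA from single eye discs of Drosophila larvae was profiled on 10 Affymetrix arrays (Drosophila 2.0), 5 from the yw control strain and 5 from GMR-upd larvae, which overexpress the JAK/STAT ligand Unpaired in the eye. Per the labels' protocols, RNA was taken from 1 disc per array with a kit for very small samples, amplified, and transcribed into biotin-labelled antisense RNA. The design text calls the 5 arrays of a genotype biological replicates. Amplification of so little RNA can change the relative signal of probe sets that lie at different distances from the 3' end of a transcript, and the array number limits the precision of every value.

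The deposited table holds 1 linear intensity per probe set and array, for 18952 probe sets including 183 controls. How the authors summarised and scaled the deposited intensities is not given in the sources used here. From the values, no log scale was applied, and array medians lay between 19.4 and 27.0, a ratio of 1.39. Because that ratio was under the limit of 1.5 set before the data were examined, intensities were used as deposited, without further normalization. No 2 arrays held the same values: at most 0.00528% of probe sets had an identical value on any pair.

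Values were analysed as log2(intensity + 16), so a fold change is on that scale and understates the change of dim probe sets. The 18769 probe sets other than controls were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene names came from the platform annotation, which can be old, and were looked up by Entrez number in a table of 17872 current genes (Release 6 assembly, used for names and gene order only). Of the tested probe sets 13647 had 1 gene, 402 had several and 4720 had no gene named here. The lookup matched 13544 of those with 1 gene, and 103 kept the annotation's symbol. A gene was represented by its probe set with the highest mean over all 10 arrays, which gave 11982 genes, of which 1094 had more than 1 probe set. Other probe sets of a named gene are given beside it where the gene was called or where their sign was opposite.

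Before the data were examined, 24 gene lists were fixed from background knowledge, covering the pathway, the Notch pathway, eye development, growth, stress, larval stage and other cell types. Of their 543 entries 428 had a probe set with that gene alone. The first lookup, by symbol only, found 422; after results had been seen, 6 more members were found under a synonym, namely Dl (listed as Delta), h (hry), Her (Hesr), CDC45L (Cdc45), Eip71CD (MsrA) and Unc-89 (Obsc), and all values were computed anew. The 22 lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01. The tests were repeated with an estimated correlation and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The lists of sex markers (0 of 2 measured) and of the transgene and strain markers (2 of 3 measured) were too short to test. Genes named in the text are upd1 and y, the 12 largest rises and the 12 largest falls among called genes whose 5 values in each genotype did not overlap, up to 4 members with the smallest p of each list, and a fixed set of pathway genes. Of that set dome, Stat92E and Delta had a probe set of their own, and N, Ser, wg, Socs36E and w were not analysed here.

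The alternatives tried were quantile normalization, median centring, dropping the dimmest 40% of probe sets, no trend, robust estimation, array weights, the replicate number as a block, the actin control's 3' minus 5' difference as a covariate, pseudocounts of 1 and 64, a 1.5-fold minimum, 1 probe set per gene, the mean of a gene's probe sets, and leaving out each array in turn. Settings that treat the arrays numbered 5 or GMR-upd array 3 apart, list members matched by symbol only, and an estimated correlation with dim probe sets dropped or an array left out, were added after seeing the data. The limma step was tested on simulated arrays made from the means and spreads of the 18769 probe sets. It called 24% of 50 probe sets changed 1.5-fold, 60% of 50 changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold, and 5.41% of its calls were unchanged probe sets. The changed probe sets were drawn only from those above the median mean level, and values varied independently with no array standing apart. These shares therefore do not cover dim probe sets or arrays such as those numbered 5. In a second simulation every measured Notch response gene was lowered by 0.5 on the log2 scale, and camera called that list and no other (adjusted p = 5.69e-34). Genes in that simulation varied independently, which makes such a shift easier to find than in real discs. Python 3.11.15 with matplotlib 3.10.9 drew the plots.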

Results

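Gene expression was measured in single eye imaginal discs, the larval tissue that forms the adult eye, from 5 yw control larvae and 5 GMR-upd larvae. GMR drives expression behind the morphogenetic furrow, the front of differentiation that crosses the disc, and upd (upd1 here) encodes Unpaired, a secreted ligand of the JAK/STAT pathway. The comparison asks which genes change in the disc when this ligand is overexpressed, and the study's title points to Notch signalling. Array medians were 19.4 to 22.4 intensity units for yw and 21.2 to 27.0 for GMR-upd, and upper quartiles ran from 55.2 to 64.3.

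Between the discs labelled GMR-upd and yw discs a limited set of genes passed the test, and further differences can have been missed. The simulation called 24% of 1.5-fold changes, and 1794 of 18769 probe sets had an unadjusted limma p under 0.05. If no gene changed, chance would still put a share of about 0.05 of all probe sets there, and the 220 called ones are included. The 1794 are therefore not a count of missed differences. The receptor gene dome and the BTB zinc finger gene chinmo, both known to rise with JAK/STAT activity in other tissues, were higher in GMR-upd. So were lama, a gene known from precursors of the visual system, and Mo25, a scaffold for protein kinases. The insulin-binding protein gene ImpL2, the peptidase gene Ance, the cuticle protein gene Cpr97Ea, the cadherin gene ds and Delta, which encodes a Notch ligand, were lower, Delta close to the threshold. In all, 115 probe sets were higher and 105 lower in GMR-upd, or 1.17% of those tested, and they stood for 81 higher and 84 lower genes.

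The probe set of the overexpressed gene, upd1 (CG5993, chromosome X), read 17.1 ± 5.4 in GMR-upd and 16.7 ± 3.7 in yw (SD, n = 5 each), a log2 change of 0.01 ± 0.11 (SE, limma adjusted p = 0.98). Both are close to the array medians, so the arrays show no rise of this probe set. Whether it lies in the part of upd1 that the transgene carries is not given in the sources used here, so it does not check the labels. The body colour gene y (CG3757, chromosome X) read 26.5 ± 2.8 and 26.4 ± 2.5.

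Of the called probe sets, 214 of 220 had 5 GMR-upd values that all lay on 1 side of the 5 yw values. Calls and this separation use the same values, so the count adds no support to the calls. Over all tested probe sets 3.50% showed it, where chance gives 0.794%. The largest rise of a gene was that of GstE13 (CG11784, 2R), a glutathione S-transferase, from 51.1 ± 10.6 in yw to 612.0 ± 147.5 in GMR-upd (SD, n = 5), 9.26-fold with a limma adjusted p of 7.06e-06. CG14598 (3R) rose from 22.4 ± 3.5 to 278.2 ± 120.1, the zinc transporter gene Zip102B (CG2177, chromosome 4) from 16.7 ± 6.7 to 177.9 ± 109.9, and Arpc1 (CG8978, 2L), a subunit of the actin-nucleating Arp2/3 complex, 4.60-fold. ATPsynepsilonL (CG31477, 3R) rose from 27.3 ± 4.8 to 210.0 ± 153.9, a wide spread. Expression of lama (CG10645, 3L) went from 91.8 ± 23.1 to 472.0 ± 177.2, 4.33-fold with an adjusted p of 0.0021. Rbm13 (CG10648, X) rose 3.98-fold and Mo25 (CG4083, 3L) 3.82-fold, from 78.5 ± 21.1 to 343.7 ± 67.6. The remaining large rises were those of chinmo (CG31666, 2L) at 3.71-fold, CG4646 (2R) at 3.66-fold, the ciliary transport gene Oseg5 (CG9333, 2L), from 19.6 ± 3.0 to 116.2 ± 43.4, and CG3257 (2R), from 16.05 ± 1.17 to 89.88 ± 25.78. For called genes no fold is given where 1 genotype's mean lay closest to the array medians, since the pseudocount then largely sets it. For CG3257 the log2 change was 2.38 with a pseudocount of 1 and 0.93 with 64. The folds that are given depend on the pseudocount too. Under 1 and 64 the log2 changes were 3.55 and 2.53 for GstE13, 2.46 and 1.29 for Rbm13, and 2.27 and 1.24 for CG4646. For chinmo, 2 further probe sets changed by 0.16 and 1.16 on the log2 scale, against 1.89 for the brightest.

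Cpr97Ea (CG6131, 3R) fell from 231.2 ± 119.4 in yw to 25.6 ± 10.1 in GMR-upd (SD, n = 5, limma adjusted p = 0.0011), close to the array medians. Pih1D1 (CG5792, 2L) fell from 358.8 ± 42.3 to 54.6 ± 20.6 and CG7137 (2R) from 257.9 ± 58.1 to 45.0 ± 18.7. ImpL2 (CG15009, 3L) fell from 938.3 ± 403.3 to 200.1 ± 78.6, a log2 change of -2.08 ± 0.34 with an adjusted p of 0.0094. Mtmr6 (CG3530, 2R), a lipid phosphatase gene, fell from 167.7 ± 20.6 to 40.9 ± 48.9; this call was lost without yw array 2 or 3 or GMR-upd array 2, and without both arrays numbered 5 (adjusted p up to 0.055). CG31937 (2L) fell from 118.5 ± 23.3 to 18.5 ± 5.1 and the centriole gene Alms1a (CG12179, X) from 112.0 ± 13.2 to 17.9 ± 3.4, and the acetyl-CoA acetyltransferase gene Acat1 (CG10932, X) had a log2 change of -1.84. CG9344 (2R), CG42749 (X), CG9662 (2L) and CG3552 (3L) lay between -1.80 and -1.74, and the other probe set of CG42749 also was lower, by -0.84. Another 42 called probe sets had no gene named here; their largest changes were rises from 6.8 to 142.4 and from 21.3 to 195.5 and falls from 567.8 to 65.2 and from 142.1 to 23.9.

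These counts depended on which arrays were used: without yw array 1, 2 or 3 the counts fell to 74, 69 or 65 higher and 64, 64 or 63 lower, and without GMR-upd array 2 to 94 and 59, whereas without GMR-upd array 5 they were 129 and 100. Of the 31 called genes named here, all with 5 of 5 GMR-upd values beyond every yw value, 25 kept their call in each of 24 other settings, and Delta, dome, rumi, Rca1, ds and Mtmr6 lost it in some. Leaving out 1 array moved the log2 change of 0 of these 31 by over 1.5 times, but that of 36 of the 77 named genes that were not called. The 31 were named as called genes, most of them for their large changes. Changes near 0 move by such a ratio easily, and a turned sign counted as a move. The 2 counts therefore do not compare how robust the genes are. Changes of uncalled genes given here can rest on 1 array.

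**Figure D1:**
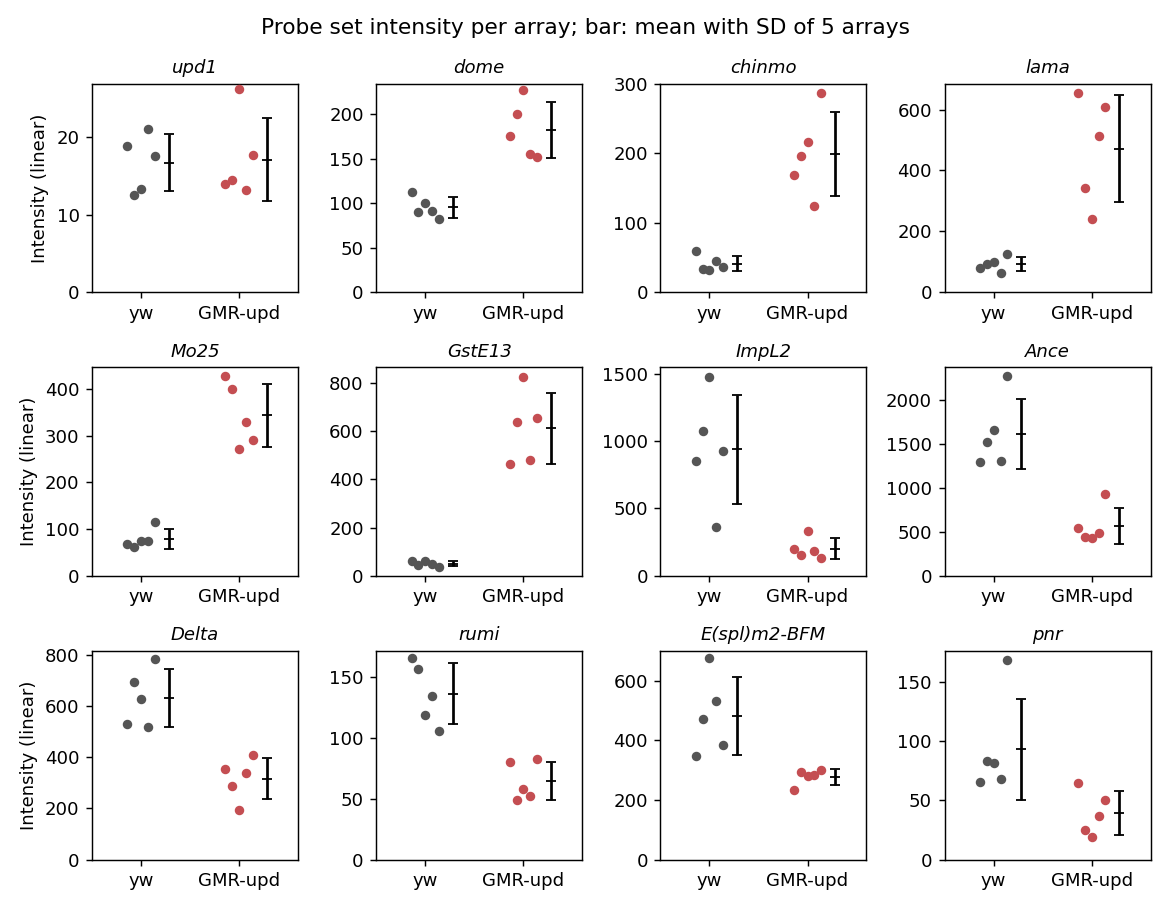
Intensity of the probe sets of 12 genes on each array (y axis, linear intensity units from 0; points are single arrays, the bar beside them the mean with the SD of 5 arrays, grey for yw and red for GMR-upd). Values of upd1 overlap between the genotypes at 16.7 and 17.1 on average, whereas those of dome, chinmo, lama, Mo25 and GstE13 are higher on all 5 GMR-upd arrays; E(spl)m2-BFM and pnr are lower on all 5 but did not pass the test.

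In the JAK/STAT pathway itself, 1 of 10 measured components passed the test over all probe sets, and 2 passed adjusted over the list alone. The receptor gene dome (CG14226, X) rose 1.77-fold, from 95.4 ± 11.7 to 182.1 ± 31.7 (SD, n = 5, limma adjusted p = 0.031). Its call was lost without any 1 yw array, without GMR-upd array 1, 2 or 4, and with the actin covariate (adjusted p up to 0.095). The transcription factor gene ken (CG5575, 2R), which passed only adjusted over the list alone, had a log2 change of 0.72 ± 0.23 (SE), with an adjusted p of 0.27 over all probe sets. Stat92E (CG4257, 3R), the pathway's transcription factor, read 109.6 ± 112.4 in GMR-upd and 95.5 ± 78.5 in yw, a spread wider than any difference; its log2 change was 0.39 without yw array 5 and -0.38 without GMR-upd array 5. The phosphatase gene Ptp61F and the receptor-like gene et had log2 changes of 0.31 and 0.11, neither past the threshold.

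Of 11 measured genes known to respond to the pathway elsewhere, dome and chinmo rose and 9 were not called, while 3 passed adjusted over the list alone, ken being the third. Positive log2 changes were found for 9 of the 11, with a mean of 0.36 and a median of 0.07. The median over all tested probe sets was 0.05, so a positive sign alone does not set a gene apart. The target list did not pass camera (p = 0.021, adjusted p = 0.073, and adjusted p = 0.29 with an estimated correlation). It passed fry, which compares it with no other genes (adjusted p = 0.0029), as did the list of components (0.021). The components share dome, ken, Ptp61F, Socs44A and Stat92E with it.

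Among 20 measured Notch response genes, mainly the E(spl) and Bearded families that Notch activity switches on, 0 were called by limma over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. That gene was E(spl)m2-BFM (CG6104, 3R), with 278.4 ± 27.0 in GMR-upd against 482.4 ± 130.6 in yw, a log2 change of -0.73 ± 0.20 (SE) and an adjusted p of 0.15. Log2 changes were 0.40 for nvy, -0.28 for E(spl)m7-HLH and 0.24 for BobA, none past the threshold. The list's mean log2 change was -0.01 and its median 0.01, with 10 members positive and 10 negative (camera adjusted p = 0.68). Of 20 measured Notch pathway components 2 fell and 18 were not called, and both also passed adjusted over the list alone. Delta (CG3619, 3R), which encodes a ligand of Notch, fell from 630.4 ± 112.4 to 316.0 ± 79.9 (SD, n = 5), a log2 change of -0.98 ± 0.21 (SE, limma adjusted p = 0.049). Its other probe set stood at -0.24 (adjusted p = 0.67), and the mean of both at -0.61 did not pass (adjusted p = 0.21). The call of Delta was lost in leaving out any 1 array except GMR-upd array 5 (adjusted p 0.056 to 0.14), without both arrays numbered 5, and with median centring, the actin covariate or a pseudocount of 64. The gene rumi (CG31152, 3R), which encodes a glucosyltransferase that modifies Notch, fell from 136.0 to 64.5 units (log2 change -0.92 ± 0.18, SE, adjusted p = 0.026). The call of rumi was lost without yw array 1, 2, 3 or 4 or GMR-upd array 2 or 4 (adjusted p up to 0.088). The changes of shi and O-fut1 were -0.28 and -0.41 on the log2 scale, with another probe set of shi at 0.61, none past the threshold, and the list did not pass camera (adjusted p = 0.073). The genes of Notch itself and of its other ligand, Ser, were not analysed here.

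For eye patterning, 0 of 12 measured dorsal eye and Wingless pathway genes were called by limma, 1 passed adjusted over the list alone, and 2 had an unadjusted p under 0.05. The dorsal selector gene pnr (CG3978, 3R) was at 39.2 ± 18.6 in GMR-upd and 93.2 ± 42.6 in yw (log2 change -0.98, adjusted p = 0.14), and mirr at 34.2 ± 13.1 and 52.4 ± 11.9 (adjusted p = 0.41). Wnt6 and Dfd had log2 changes of -0.35 and 0.34, and the list's camera adjusted p was 0.073. Of 15 retinal determination genes chinmo was the 1 that rose, and dan, toy and Optix, with log2 changes of -0.47, -0.32 and -0.56, did not pass; another probe set of toy stood at 0.08. That list's camera direction was down (adjusted p = 0.68) although its mean and median were 0.10 and 0.06. None of 17 genes of the furrow (unadjusted p under 0.05 for 0; limma) or of 31 photoreceptor and EGFR genes (3 unadjusted) was called. In these 2 lists the smallest p belonged to rn, ro, emc and da, between 0.18 and 0.42, and to pros, sty, svp and S, at 0.91, 0.49, -0.40 and 0.46 on the log2 scale; camera adjusted p-values were 0.68 for both.

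Genes of growth and survival gave single calls. In the cell cycle list Rca1 (CG10800, 2L), an inhibitor of cyclin destruction, rose from 194.1 ± 31.8 to 374.7 ± 51.1 (1.86-fold, adjusted p = 0.026) and 28 of 29 genes were not called, among them aurB, fzy and Cdk4 at -0.66, -0.52 and -0.65 on the log2 scale, with other probe sets of fzy at 0.03 and 0.13. Without GMR-upd array 3 the changes of fzy and Cdk4 were -0.32 and -0.27. The call of Rca1 was lost without yw array 1, 2 or 3, GMR-upd array 1, 2, 4 or 5, or both arrays numbered 5, and with median centring (adjusted p up to 0.0996). In the Hippo pathway list ds (CG17941, 2L), which encodes the cadherin Dachsous, fell from 117.7 ± 22.6 to 44.6 ± 18.8 (log2 change -1.18, adjusted p = 0.017) and 17 of 18 were not called, with Mer, crb and wts at -0.31, -0.51 and -0.31. Without yw array 1, 2 or 4 or GMR-upd array 2 the call of ds was lost (adjusted p up to 0.057). Of 18 apoptosis genes 0 were called by limma (3 at an unadjusted p under 0.05) and 1, skl, passed adjusted over the list alone at a log2 change of 0.26 (adjusted p = 0.063 over all probe sets, 0.038 without GMR-upd array 5). Bruce, grim and Diap2 had changes of -0.24, 0.24 and -0.51. Of 41 ribosomal protein genes RpS5b (CG7014, 3R), a paralog known from germ cells, rose from 22.2 ± 2.2 to 81.9 ± 31.2, and 40 were not called. Among these, RpL36A, RpL37-1 and RpS15 were at 0.24, -0.44 and -0.24. None of 19 Myc and nucleolar genes passed limma (0 at an unadjusted p under 0.05), with Ns2, Tif-IA, kra and eIF3b between -0.26 and 0.18. Camera adjusted p-values of these 5 lists, in this order, were 0.64, 0.073, 0.68, 0.074 and 0.67.

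Of 24 ecdysone and stage genes, ImpL2 fell and 23 were not called; Blimp-1, ftz-f1 and Edg78E had log2 changes of -0.96, 1.19 and 0.29. The list of 18 heat shock and stress genes held no call by limma (4 at an unadjusted p under 0.05), with Hsp26, Hsp27, GstD1 and crc at -0.74, -0.67, -0.63 and -0.36. Both lists had a camera adjusted p of 0.073. Among 19 immune genes there were 0 calls (3 unadjusted), and spz, PGRP-SB1, Dif and Rel stood at 0.50, 0.27, 0.39 and -0.44 on the log2 scale (camera adjusted p = 0.65).

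Markers of other cells did not separate the genotypes as lists. Of 19 haemocyte genes Ance (CG8827, 2L) fell from 1612.8 ± 400.7 to 568.3 ± 206.7 (log2 change -1.51, limma adjusted p = 0.0048), and 18 were not called. Ance encodes a homologue of angiotensin-converting enzyme. It read 1300 on yw array 1 and 1657 on yw array 3, where PPO1 read 948 and 7.19 and Hml 99.2 and 33.3. In each genotype, however, both Ance and Hml were highest on the array numbered 5. Which cells the fall of Ance concerns was not determined. Pvr, crq and ush were at -0.27, -0.28 and 0.29. For glia (16 genes), neuronal maturation (20), antenna and peripodial membrane (20), fat body (16) and muscle (13), limma called 0, and 3, 3, 2, 1 and 0 genes had an unadjusted p under 0.05. Glial Mdr65, moody, alrm and Vmat stood at -0.52, -0.49, 1.13 and -0.24, and neuronal cac, futsch, Snap25 and Csp at 0.34, 0.81, 0.25 and 0.35. Other probe sets of Vmat lay between 0.04 and 0.24. The change of alrm was 0.74 without GMR-upd array 1. Mdr65 passed without GMR-upd array 3 (adjusted p = 0.0087) and cac without yw array 2 (0.042). Antennal ems and Doc3 with dac were at 0.50, -0.28 and 0.47, fat body Fbp2, Lip3, Obp44a and Pepck1 at 0.94, 0.24, 0.92 and 0.57, and muscle Act87E, TpnC73F, up and Prm at -0.33, -0.22, -0.64 and 0.42, with another probe set of Prm at -0.53. Single arrays carried several of these: without yw array 1 up was at -0.07 and Act87E at -0.12, without yw array 4 Obp44a at 0.37, without GMR-upd array 2 Fbp2 at 0.60, and without GMR-upd array 3 Pepck1 at 0.24 and Prm at 0.13. Single discs varied in such markers within a genotype: fat body Lsp2 ran from 8.81 to 1131 units in yw and from 31.1 to 1029 in GMR-upd, and muscle Tm2 reached 628 on yw array 1 against at most 83.0 on the other 9 arrays. Camera adjusted p-values for haemocytes, glia, neuronal maturation, antenna, fat body and muscle were 0.35, 0.32, 0.073, 0.68, 0.40 and 0.15.

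Over all 22 lists, camera called 0, with 8 at an unadjusted p under 0.05 (3 with an estimated correlation, where 0 passed adjustment). Asked for movement one way, fry called 2. Asked for changes in either direction, fry passed retinal determination (adjusted p = 8.28e-08), JAK/STAT targets (5.89e-06) and JAK/STAT components (0.00096). It also passed Notch components (0.0080) and apoptosis (0.029). The first 2 of these share chinmo, and fry compares a list with no other genes. The number depended on single arrays: without GMR-upd array 4 camera called 3 lists (Notch components, Hippo, heat shock), without yw array 4 it called these and the ecdysone list, 4 in all, and without GMR-upd array 5 these 4 and the dorsal eye, ribosomal and haemocyte lists, 7 in all. These calls were made with the preset correlation, and with an estimated one 0 lists passed without any 1 array (adjusted p 0.26 to 0.55 for those named). The size of the correlation alone does not account for the loss. Over all arrays the heat shock list's estimate was -0.005, below the preset 0.01, yet its camera p went from 0.0098 to 0.023. For the Notch response, cell cycle and haemocyte lists the mean was negative and camera's direction down while the median was positive. For the retinal determination and the Myc and nucleolar lists mean and median were positive and camera's direction was down. Camera compares a list with the other genes, and the median log2 change over all tested probe sets was 0.05, not 0.

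**Figure D2:**
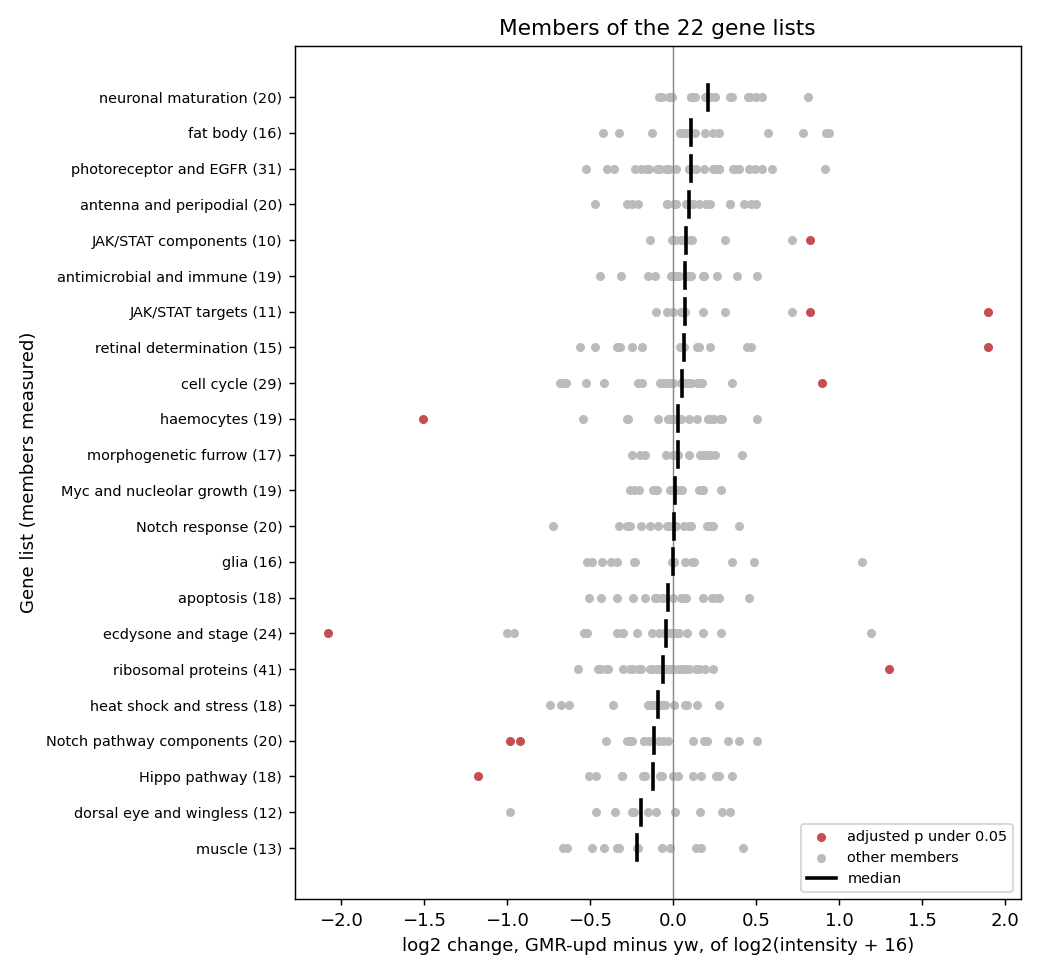
Log2 change (x axis, GMR-upd minus yw, of log2(intensity + 16)) of every measured member of 22 gene lists (y axis, with the number measured); red points passed an adjusted p of 0.05 and black bars are medians. Most lists hold 0 or 1 called gene and have medians near 0, with JAK/STAT targets and Notch pathway components holding 2 called genes each and Notch response 0.

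The first component over the 11261 brighter probe sets held 35.4% of the variance and set both arrays numbered 5 apart from the other 8, and the second, with 27.7%, set GMR-upd arrays 3 and 5 apart, at -40.4 and -30.8 against -8.37 or higher. On the second, yw arrays 1 to 4 lay above every GMR-upd array, and on the third, with 12.3%, all 5 yw arrays were positive and 4 of 5 GMR-upd arrays negative. The correlation of GMR-upd array 3 with the others had a median of 0.894, against 0.926 to 0.962 for the other 9. The brightest probe set of the ecdysone-responsive gene ImpE1 read 699 and 568 on the yw and GMR-upd arrays numbered 5 and 23.4 to 90.3 on the others, a log2 change of 3.26, whereas its 3 other probe sets changed by 0.41, -0.01 and 0.34.

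**Figure D3:**
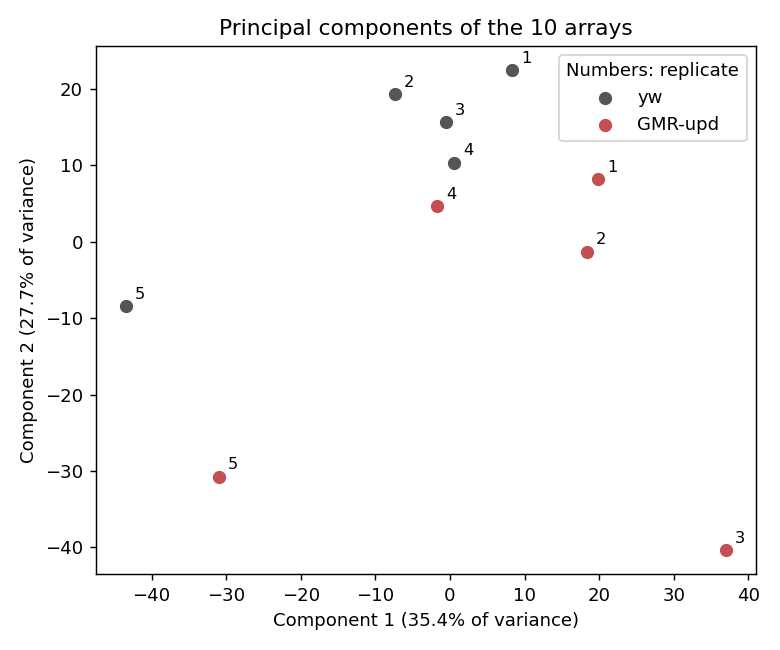
The 10 arrays on the first (x axis, 35.4% of variance) and second (y axis, 27.7%) principal components of log2(intensity + 16), grey for yw and red for GMR-upd, with the replicate number beside each point. Both arrays numbered 5 lie at the left, GMR-upd arrays 3 and 5 lie lowest, and the remaining 7 lie closer together, with yw arrays 1 to 4 above every GMR-upd array.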

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

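Tests chosen only after the result was seen were those of RNA amplification, larval stage, probe set variants, antennal tissue and spike controls. Of these, 3 replaced an earlier test after its result was known. For amplification, the earlier test was the correlation, across 529 genes, of a gene's 2 probe sets; it gave 0.045, but the genotype comparison, at 0.29, met its bound as well, and most of these genes were not called. For variants, the median over all other probe sets was 0.14 and lay between its bounds. For antennal tissue, 2 of 20 had been taken as the chance number, although 32.7% of all genes were highest on GMR-upd array 3.

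Of 248 groups of 5 values examined, 25 held a value far from the other 4, where chance flags about 1 in 20 groups, or 12.4; 7 were on yw array 5, 7 on GMR-upd array 3 and 4 on GMR-upd array 5.

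On yw array 5, CG4646 read 21.9 intensity units (35.5 to 37.8 on the other yw arrays), Pih1D1 286, pnr 168, S 75.5 and crq 63.9. The glial list's mean there was 6.87 on the log2 scale (6.36 to 6.40 on the others), and the GAPDH control's 3' minus 5' difference was 4.96. On GMR-upd array 5, Oseg5 read 43.3 (112 to 153 on the other GMR-upd arrays), eIF3b 950 and crq 59.4, and the cell cycle list's mean was 7.61. On GMR-upd array 3, Mtmr6 read 128 (14.8 to 22.4 on the others), svp 31.0, grim 20.5, RpL36A 4523, PGRP-SB1 48.6 and Mdr65 51.8, and the array median was 27.0. Elsewhere, CG3257 read 14.0 and the muscle list's mean was 7.13 on the log2 scale on yw array 1, Ptp61F 223, cac 35.2 and Edg78E 17.9 on yw array 2, sty 595 on yw array 3, and E(spl)m2-BFM 232 on GMR-upd array 1.

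The 2 arrays numbered 5 stand apart from the other 8, 1 of each genotype, with 968 probe sets higher and 406 lower by limma; of genes central to eye development, gl and eya were 2.73 and 2.62 higher on the log2 scale, whereas so read 106 and 100 there against 77.6 to 132 elsewhere, and the retinal determination list had a median of 0.07 with 3 of 15 genes called. Amplification that reached to another place along transcripts remains open: over 100 other probe sets of the genes called here, the median change in the called direction was 0.014 (bootstrap bounds -0.045 to 0.061) where the genes' own median was 0.91. The eIF-4a control's 3' minus 5' difference was highest on these arrays, at 5.63 and 5.83, with GMR-upd array 3 close at 5.52. The actin control's was instead the lowest of all arrays on yw array 5, at 5.66. On GMR-upd array 5 it was 6.20, within the 6.06 to 7.34 of the other 8. The GAPDH control's was not highest on these arrays either, at 4.96 and 4.65 against 5.14 on GMR-upd array 2. A later stage may contribute, with the ecdysone list shifted upwards (camera p = 0.0101, 0.037 with an estimated correlation; median 0.11, 4 of 24 genes called), but the shift was not particular to it: haemocytes (1.33e-05), retinal determination (0.0072), photoreceptor (0.0081) and Notch component genes (0.0082) passed too, with 0.062 to 0.30 by an estimated correlation, where glia, at 0.0198, had 0.041, and the labels describe equally aged larvae. Each genotype has 1 such array, so no biological explanation from the design was tested.

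Between the genotypes 156 genes outside the fixed lists were called, 1.35% of such genes, against 9 or 2.22% of the 406 within. In 100 splits of the 10 arrays the real one gave 115 higher and 105 lower, and the highest other gave 15 in a direction. Thus 1 of 100 splits, the real one, reached either count, the fewest this test can give. It argues against chance as the source of the counts as a whole, but does not show which single calls are false. The splits took no account of the replicate numbers. Chromosome segments that differ between the strains remain open. On an arm, 19 pairs of called genes lay within 5 measured genes of each other, against a median of 11 in 10000 draws matched on expression (permutation p = 0.0153). Unmeasured genes between them were not counted. But the spread of calls over the arms gave a permutation p of 0.278, and 8 of the 19 moved the same way. Neighbours such as CG11147, CG11029 and obst-E, named after their values were seen, count as several pairs. A base variant under 1 probe set cannot be told apart from a change of the gene, since 23 other probe sets followed by a median of 0.19 (bootstrap bounds 0.12 to 0.52) where the genes' own median was 1.08. The effect of the ligand, which the design names, stays open and untested against these.

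GMR-upd array 3 stands apart by its median correlation with the other arrays, 0.894 against 0.926 to 0.962 for the other 9. An array-wide difference in brightness was tested only weakly, since a correlation across probe sets responds little to it. After quantile normalization this array's median correlation was 0.895, still below the lowest of the others, 0.927. The low correlation thus remained once all arrays had the same distribution of values, which does not decide whether brightness contributed. Antennal tissue taken along with the disc may contribute: 10 of 20 measured antenna and peripodial genes were highest on this array, against a median of 6 in matched draws (permutation p = 0.0403), 5 of the 20 also being in another list. The antennal genes Dll and ss read 129 and 87.3 there against at most 41.9 and 24.8 elsewhere, and dac and danr, the brightest probe sets of the list and also eye genes, read 718 and 126 there against 422 to 1416 and 82.9 to 454 elsewhere; brightness of different probe sets does not rank transcripts. Less amplified RNA cannot be told apart, since the array's spike controls ranked 2 of 10 and yw array 4, which ranked higher, did not stand apart; no biological explanation within the eye disc was tested.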

How the results depend on the processing

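Settings that treat the arrays numbered 5 or GMR-upd array 3 apart, the lookup of list members, and an estimated correlation with dim probe sets dropped or 1 array left out, were chosen after seeing the data; the others were fixed before. The counts of probe sets higher in GMR-upd (115) and probe sets lower in GMR-upd (105) went to 220 and 177 with array weights, all earlier calls included, and to 190 and 167 with the arrays numbered 5 as a block; the cause was not tested. They went to 172 and 141 without both arrays numbered 5 and GMR-upd array 3. Leaving out 1 array at a time gave 65 to 132 higher and 59 to 100 lower, and 0 to 7 gene lists. The replicate block gave 149 and 123 and no list; the numbers were not taken as pairs, since 4 and not all 5 same-numbered pairs correlated over 0.1 and 3 of 5 yw arrays matched their own number best. Dropping the dimmest 40% of probe sets let 2 lists pass, JAK/STAT targets (mean log2 change 0.44, adjusted p = 0.038) and neuronal maturation, but 0 with an estimated correlation (adjusted p = 0.39 for both), as in leaving out 1 array; fry let 2 pass, JAK/STAT targets at an adjusted p of 0.0029 and the components. With list members matched by symbol only, as at first, 0 lists passed, and the Notch components mean was -0.06 (adjusted p = 0.17) in place of -0.11. Over 38 settings the JAK/STAT targets mean stayed between 0.26 and 0.44 (adjusted p 0.0029 to 0.41) and passed in 2, and the Notch response mean between -0.08 and 0.01 (adjusted p 0.57 to 0.99) and passed in 0. The upd1 change ran from -0.11 to 0.06, so its sign turned while it never passed. No named gene or list past the threshold turned its direction; calls of 25 of 31 named genes held throughout, and that of Delta in 10 of 24 settings. Uncalled genes passed in places: skl, GstD1 and Mdr65 with array weights and without both arrays numbered 5 and GMR-upd array 3, skl also with mean probe sets, mirr without those 3 arrays, and pnr with the arrays numbered 5 as a block; the cause was not tested. A roX2 covariate was not run, because roX2 was not analysed here. The sex of the single discs is unknown and neither marker of the sex list was measured. Whether a difference in sex between the groups lies behind some genotype calls was therefore not tested. With dim probe sets dropped upd1 gave no value. Probe sets near the array medians, such as those of upd1 and skl, lie close to background, which limits any change seen there.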

Other observations

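The family tests below were chosen after the data were seen. Families of genes that share the start of their symbol gave no group past the threshold: of 61 families with at least 10 genes, camera called 0 after adjustment, with an unadjusted p under 0.05 for 13. The lowest p-values belonged to the proteasome regulatory subunits (Rpn, 12 genes, median log2 change -0.11, camera adjusted p = 0.20), the large-subunit ribosomal proteins (RpL, 21 genes, median -0.07) and the Osi genes (24 genes, median 0.09).

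Single discs differed in the signal of genes known from other larval tissues. The prophenoloxidase genes PPO1 and PPO2, made by crystal cells of the blood, ran from 7.19 to 948 and from 18.4 to 1145 units over the yw arrays, and from 38.0 to 873 and from 45.9 to 836 over the GMR-upd arrays. The salivary glue genes Sgs7 and Sgs8 reached 736 and 580 on yw array 2 and at most 129 and 158 on the other 9. The muscle genes Mf, bt and Mlc1 read 569, 614 and 374 on yw array 1 and at most 92.5, 96.6 and 57.7 elsewhere. The glial gene repo was between 83.5 and 229 on all 10 arrays.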
